A study of Homo sapiens with 21 samples.

How the data were processed

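Expression was measured with Affymetrix whole-transcript gene arrays in U-87MG, an established human glioblastoma cell line, in clones that stably carried either parkin or the empty vector. The deposited table held 26947 probe sets on 21 arrays, 12 of vector clones and 9 of parkin clones. Its values are RMA intensity, which the authors deposited on a linear scale; RMA is named per the labels without a version, and whether all arrays were normalized together is not stated. The values were turned into log2 values, with no missing value and no pair of identical columns. Array medians lay between 6.21 and 6.37 on the log2 scale. Arrays have no counted depth, so the number of arrays and clones limits the precision.

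The labels name 3 vector clones, V8, V17 and V22, and 3 parkin clones, PK7, PK19 and PK25, each with 3 arrays per series. The scanner file names of the arrays differ in their prefix, which was read here as a first and a second series. That reading and the order of the series are assumptions. V8 and V17 were measured in the first series only, the parkin clones in the second only, and V22 in both. Group and series were therefore linked through V22 alone. For every probe set, the mean of the 3 V22 arrays of the first series minus the mean of the 3 V22 arrays of the second was subtracted from all arrays of the first series. The set numbers did not pair vector arrays of the first series with parkin arrays, and pairing of V22 arrays of the second series was not tested. Within the first series, arrays of the same set correlated at 0.0591 to 0.216 and arrays of different sets at -0.141 to 0.0533. For parkin arrays these correlations were -0.0917 to 0.381 and -0.365 to 0.323. A fit with the set number as a replicate block is given with the alternatives.

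Gene symbols came from the annotation table of the array. It gave 1 symbol for 19305 probe sets (18374 genes), several symbols for 1750, and did not list 5892. The gene IDs of 31 probe sets matched no current gene. The transcript level of the introduced gene was not analysed here. Chromosomes and neighbouring genes were taken from the RefSeq annotation of GRCh38.p14, and no positions from it are given.

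The main comparison used limma 3.58.1 (lmFit, eBayes) in R 4.3.3 on the 6 clone means, 3 against 3, with Benjamini-Hochberg adjusted p under 0.05 over all probe sets and no filter. The clone was the replicate, because arrays of a clone may be technical repeats. Other limma comparisons were the parkin clones against V22 within the second series (clone means, with the lone vector clone assumed to vary like the parkin clones), an F test among the 3 parkin clones and among the 3 vector clones, each clone against V22 of its own series (adjusted p under 0.05 and at least 2-fold), and V22 between the series. These last comparisons used arrays as observations, so their p-values measure only the spread between arrays. Because limma called no probe set between V17 and V22, vector means with an SD are given over V8 and the mean of V17 and V22 (n = 2), and the comparison was repeated with V17 and V22 counted once, a choice made after the data were seen.

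Before the data were examined, 44 gene lists were fixed, covering the cell cycle, stress and metabolism, signalling, glioma subtypes, mitochondria, protein turnover and markers of other cell types. Lists with at least 5 measured genes, 43 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest), and again with an estimated correlation. In each list, p-values were also adjusted over the list alone. Named genes followed a rule set before the data were examined. Among probe sets with 1 symbol, clone means of the groups apart and the same sign within the second series, the rule took those past the threshold, and filled up to 12 rises and 12 falls by smallest p. From each list it took up to 4 members past the threshold, or the 2 with the smallest p. From each F test it took the 5 largest F values. For each clone against V22, up to 12 genes each way with the largest change were listed, a rule added after the data were seen.

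The position of genes was examined after the data were seen. For the 8717 placed genes with a mean log2 value above 7, the difference between a clone and V22 was compared between genes 10 places apart on a chromosome, against 999 permuted gene orders. Medians were taken over runs of about 50 neighbouring genes. In an alternative, each array's running median over 50 neighbours relative to V22 was subtracted, and for histone genes this was repeated with neighbours that are not histone genes.

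Alternatives planned before the data were examined changed 1 choice at a time, apart from vector arrays of the first series alone, used without adjustment for the series, and the set-number block, which also took arrays as observations, used sets 1 to 3 and left out that adjustment. They covered the adjustment for the series, the vector arrays used, arrays as observations with clone as a random block (duplicateCorrelation, statmod 1.5.0) or as fixed terms, a set-number block, quantile normalization, median centring, leaving out the dimmest 30% of probe sets, a trended and robust variance, 1 probe set per gene, no fold threshold or an added one, and leaving out each clone, set or array. Others were chosen after the data were seen: V17 and V22 counted once, leaving out the set 2 arrays and V22 set 5, set-number blocks in the F tests and clone comparisons, the subtraction of neighbours, and single arrays of the first series left out.

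The code was tested on simulated data of the same layout. For parkin against vector clone means (26947 probe sets), limma called 63.5% of probe sets made to change by 1 on the log2 scale, 97.1% of those changed by 2 and 98.5% of those changed by 4, with 17 false calls. Of the unchanged probe sets, 11.0% had an unadjusted p under 0.05. With V17 and V22 counted once, 46.0% of the changes of 1 were called. Changes of 1 were planted together with changes of 2 and 4, which eases the adjusted threshold, and V17 and V22 were simulated as independent clones. In the data 159 probe sets differed by at least 2-fold and 1 was called. The simulated shares therefore do not tell how many changes of 1 would be found in the data. For a single clone against V22, 86.1% of changes of 1 passed the adjusted p alone, without the 2-fold threshold. With both thresholds there were 3 false calls. For the F test among parkin clones, 91.7% of changes of 1 passed, with 13 false calls, and for V22 between series 81.9% passed, with 7 false calls. A list shifted by 0.5 gave p = 1.9e-31 by camera with the preset correlation and p = 1.6e-04 with an estimated one. With the preset correlation, 2 of 100 unshifted lists had a p under 0.05. Simulated genes varied independently of each other, so this does not test the preset value where genes of a list vary together. In the lists called in the data, the estimated correlation ran from 0.031 for interferon response to 0.682 for histones. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.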

Results

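Gene expression was measured on 21 arrays of U-87MG, a human glioblastoma cell line, in 3 clones carrying an empty vector (V8, V17 and V22) and 3 clones carrying parkin (PK7, PK19 and PK25). Each clone had 3 arrays in a series. The 9 parkin arrays belonged to the second series, as the prefixes of the array file names were read here. The vector arrays comprised 9 arrays of the first series and 3 further arrays of V22 in the second. Each array gave RMA intensities of 26947 probe sets, used as log2 values. The transcript of the introduced gene was not analysed here. Arrays of a clone may be technical repeats, so p-values computed over arrays measure only the spread between arrays.

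Parkin is a ubiquitin ligase that marks damaged mitochondria for removal, and the comparison of parkin with vector clones asked which transcripts differed with the introduced gene. Probe set 8130645, which the annotation table gives no gene for, was at 9.41 ± 0.18 (SD, n = 3 clones) in parkin clones and 4.76 ± 0.015 (SD, n = 2, with V17 and V22 as 1 sample) in vector clones. Its log2 difference was 4.66 (SE 0.11, limma adjusted p = 6.8e-05), and it was higher in 3 of 3 parkin clones. Within the second series the difference was 4.59. Over 18 settings its adjusted p ranged from 2.6e-13 to 0.0031. No gene with a symbol passed the threshold.

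CTSD, which encodes the lysosomal protease cathepsin D, was at 12.05 ± 0.27 (SD, n = 3) in parkin clones and 11.05 ± 0.012 (SD, n = 2) in vector clones, a log2 difference of 0.99 (SE 0.14). IFITM10 differed by 1.45 (SE 0.24), PLAAT3, a phospholipase gene, by 0.96 (SE 0.13) and EPB41L1, a membrane skeleton gene, by 0.88. Smaller positive differences were 0.63 for HSD17B7P2 and 0.41 for MFSD6L. Among dim probe sets, ORM2 differed by 0.99, TARP by 0.64, FABP4 by 0.63, ZNF10 by 0.56, BRINP1 by 0.47 and FSCB by 0.40, of which ORM2 stood at 0.03, TARP at 0.08, BRINP1 at 0.11 and FSCB at -0.02 with vector arrays of the first series alone. Of the 12 negative differences chosen by p, the largest was that of SULT1B1, a sulfotransferase gene with a dim probe set (-1.84, SE 0.15, adjusted p = 0.12). POLE2, a subunit of DNA polymerase epsilon, differed by -0.77 (SE 0.11), and FANCM, a DNA repair helicase gene, by -0.61. NSD2, a histone methyltransferase gene, differed by -0.59, and PDS5A, a cohesin regulator gene, by -0.44. The remaining negative differences were -0.89 for DPY19L2, -0.88 for ZEB2 (a dim probe set), -0.86 for MOK, -0.76 for SNORA28, -0.56 for TPT1, -0.48 for NIP7 and -0.47 for CHCHD3. ZEB2 and TPT1 each have a brighter probe set, whose value is not given here. Their differences therefore belong to the probe set rather than to the gene. Of these 24 genes, all but SULT1B1 had an adjusted p of 0.306, 8 were among the dimmest 30% of probe sets and 5 lay on chromosome 14 (FSCB, SNORA28, FANCM, POLE2 and MOK). With vector arrays of the first series alone, HSD17B7P2 stood at 0.21, MFSD6L at 0.27, PDS5A at -0.16, CHCHD3 at -0.29, ZEB2 at -0.34, TPT1 at -0.37, DPY19L2 at -0.44 and SULT1B1 at -1.01.

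In the parkin against vector comparison limma called 1 probe set, and 3787 probe sets (14.1%) had an unadjusted p under 0.05. In the simulation 11.0% of unchanged probe sets had such a p. The vector clone means share the link through V22, so the SE and p-values of this comparison do not fully hold its error. The clone means of the groups were apart in 6236 probe sets (23.1%, where chance gives 10% for independent clones, a condition that V17 and V22 and their shared link between series do not meet), 3303 higher and 2933 lower in parkin clones. With V17 and V22 counted once, limma called the same probe set (adjusted p = 0.0031). After subtraction of the running median of neighbouring genes, FANCM differed by -0.21, POLE2 by -0.45, PDS5A by -0.24, CHCHD3 by -0.27 and FSCB by 0.82. The count was 38 without PK25 and 3 without V8, and with arrays as observations it was 22 with clone as a random block, 885 with clones as fixed terms, and 1343 with a set-number block and no adjustment for the series.

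**Figure D1:**
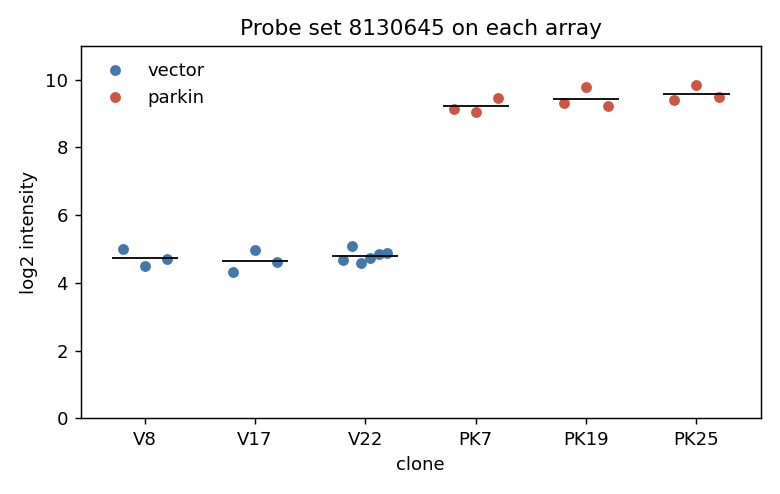
Log2 intensity of probe set 8130645 on each of the 21 arrays by clone (blue vector, red parkin), with a line at the mean of each clone. All parkin arrays lay above all vector arrays, around means of 9.41 and 4.76 for the groups.

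Genes of DNA replication fell in parkin clones, with 30 of 31 measured genes lower and a median log2 difference of -0.29. By limma's camera their adjusted p was 2.9e-11 with the preset correlation, and adjusted p = 0.78 with an estimated correlation. Adjusted over the list alone, 11 of them passed, and none of them in this way with V17 and V22 counted once. These were POLE2, GINS3 (-0.52) and RFC2 (-0.50), GINS2 (-0.43), PRIM1 (-0.41), RFC5 (-0.35), MCM7 (-0.34), GINS1 (-0.32), CDT1 (-0.31), RFC4 (-0.30) and RFC3 (-0.29), which encode polymerase, primase, clamp loader and helicase components, apart from CDT1, an origin licensing gene. Genes of G2 and mitosis fell with a median of -0.11 and 28 of 37 lower (camera adjusted p = 5.5e-04, and adjusted p = 0.78 with an estimated correlation), among them CENPE, a kinetochore motor gene (-0.55, SE 0.15), and CDK1 (-0.41, SE 0.11). Within the second series the median of G2 and mitosis was -0.05. In the vector clone V17 against V22 it was 0.14 (camera adjusted p = 2.8e-08, and adjusted p = 0.98 with an estimated correlation). Replication-dependent histone genes fell with a median of -0.24 and 28 of 31 lower (camera adjusted p = 0.0033, and adjusted p = 0.78 with an estimated correlation), including H4C4 (-0.67) and H2AC8 (-0.31). None of the 31 histone genes had the clone means of the groups apart, and against V22 the vector clone V8 had a histone median of -0.60, where PK7 had -0.59, PK19 -0.42 and PK25 -0.23. Ribosomal protein genes fell with a median of -0.08 and 36 of 44 lower (camera adjusted p = 0.0039, and adjusted p = 0.78 with an estimated correlation), including RPL31 (-0.48) and RPL23 (-0.21). In the latter 3 lists no gene passed when adjusted over the list alone, with smallest adjusted p of 0.131, 0.513 and 0.232.

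On the PK7 set 2 array the mean of the DNA replication list was 8.98, where the other parkin arrays had 9.34 to 9.56. Without the set 2 arrays and V22 set 5, the DNA replication list kept its call with a median of -0.25, and the list of G2 and mitosis lost it (median -0.03, adjusted p = 0.387). The median of G2 and mitosis was -0.17 without PK19 and -0.05 after quantile normalization, and it was -0.06 without adjustment for the series. The histone median was -0.40 without V8 and -0.47 without adjustment for the series, and the call was lost without PK7 (median -0.12, adjusted p = 0.134), V17 (-0.14, 0.101) or V22 (-0.18, 0.190) and with V17 and V22 counted once (-0.16, 0.155). The 31 histone genes all lie on chromosome 6, and 26 or 27 of the 50 nearest expressed genes of each were histone genes themselves. With histone genes left out of the neighbours, the median was 0.02 after subtraction of their running median (adjusted p = 0.886). The call of ribosomal proteins was lost without PK7 (median -0.06, adjusted p = 0.143) or without adjustment for the series (-0.05, 0.136), and with vector arrays of the first series alone (0.270) or the set-number block (0.273), both without that adjustment. Over all settings the adjusted p ranged from 1.0e-13 to 0.780 for DNA replication, 4.2e-05 to 0.780 for G2 and mitosis, 3.2e-13 to 0.886 for histones and 0.0018 to 0.780 for ribosomal proteins.

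Targets of hypoxia-inducible factor were higher in 25 of 25 measured genes between the groups, with a median log2 difference of 0.46 (camera adjusted p = 4.9e-08 with the preset correlation, and adjusted p = 0.78 with an estimated correlation). Against V22 the list median was 0.73 in PK7, 0.84 in PK19, 0.05 in PK25 and 0.01 in V8. DDIT4, an mTOR inhibitor gene, differed by 1.18 (SE 0.30) and ANKRD37 by 0.35 (SE 0.10). Before adjustment for the series, V22 had DDIT4 at 8.03 in the first series and 6.78 in the second. Parkin clones had a mean of 7.91, so the DDIT4 difference depended on the series of the vector arrays. Glycolysis genes rose with a median of 0.34 and 21 of 24 higher (camera adjusted p = 4.0e-04, and adjusted p = 0.78 with an estimated correlation), including HK2, a hexokinase gene (0.86, SE 0.30), and TPI1 (0.49, SE 0.15). Their medians against V22 were 0.37 in PK7, 0.65 in PK19, 0.07 in PK25 and 0.08 in V8.

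Antioxidant targets of NRF2 rose with a median of 0.19 and 26 of 27 higher (camera adjusted p = 0.0034, and adjusted p = 0.78 with an estimated correlation), including ABCC3, an efflux pump gene (0.67), and AKR1C1, an aldo-keto reductase gene (0.60). Against V22 their medians were 0.48 in PK7, 0.14 in PK19, 0.11 in PK25 and 0.24 in V8. The list of NF-kB genes, which holds cytokines, chemokines and other genes, rose with a median of 0.20 and 27 of 35 higher (camera adjusted p = 0.034, and adjusted p = 0.78 with an estimated correlation). It included ICAM1, an adhesion molecule gene (1.54), and TNFAIP2 (1.15), neither of them a cytokine or chemokine. Interferon response genes rose with a median of 0.10 and 31 of 41 higher (camera adjusted p = 0.019, and adjusted p = 0.78 with an estimated correlation), including IFI35 (0.41) and IFIT2 (0.39). Genes of autophagy and the lysosome rose with a median of 0.13 and 27 of 36 higher (camera adjusted p = 0.046, and adjusted p = 0.78 with an estimated correlation). In that list CTSD passed when adjusted over the list alone (adjusted p = 0.0085), a call lost with V17 and V22 counted once, and CTSL, another cathepsin gene, differed by 0.42. In the other lists that rose no gene passed when adjusted over the list alone, and the smallest such adjusted p of hypoxia targets was 0.0786.

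The V22 set 2 array had a hypoxia list mean of 9.43, where the other V22 arrays had 8.63 to 8.92. Without the set 2 arrays and V22 set 5 the hypoxia median was 0.18 (adjusted p = 0.00080), that of glycolysis 0.11 (adjusted p = 0.026) and that of NRF2 0.12 (adjusted p = 0.014), and autophagy and lysosome lost its call (median 0.08, adjusted p = 0.208). Without adjustment for the series the calls of hypoxia (median 0.20, adjusted p = 0.066), glycolysis (0.10, 0.170), NF-kB (0.12, 0.201), interferon (0.08, 0.240) and autophagy and lysosome (0.04, 0.554) were lost, and the NRF2 median was 0.37. With vector arrays of the first series alone the hypoxia median was 0.12 (adjusted p = 0.270), and these 5 lists were lost there and with the set-number block as well, both without that adjustment. Over all settings the adjusted p of these 6 lists reached 0.780, and the smallest was 7.0e-18 for hypoxia, 5.3e-08 for glycolysis, 1.0e-08 for NRF2, 0.0012 for interferon, 5.7e-06 for NF-kB and 2.9e-04 for autophagy and lysosome.

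Leaving out PK7 ended the calls of NRF2 (median 0.06, adjusted p = 0.257), interferon (0.11, 0.134), NF-kB (0.11, 0.183) and autophagy and lysosome (0.07, 0.413). Leaving out PK19 ended those of NF-kB (adjusted p = 0.130) and autophagy and lysosome (0.161), and leaving out V8 that of interferon (0.167). Leaving out V17 ended NF-kB (0.131) and autophagy and lysosome (0.114), and leaving out V22 ended the same 2 lists (0.241 and 0.190). The median of hypoxia targets was 0.79 without PK25 and 0.29 without PK19, and that of glycolysis 0.54 and 0.21. The NF-kB median was 0.38 without PK25, 0.32 without V8 and 0.36 without the dimmest 30% of probe sets, and the NRF2 median 0.31 without V8. After subtraction of the running median of neighbouring genes the median was 0.29 for NRF2, 0.34 for NF-kB and 0.17 for interferon, and with arrays centred on their medians that of interferon was 0.06. With V17 and V22 counted once, 7 lists passed in place of 10, without histones, NF-kB (adjusted p = 0.185) and autophagy and lysosome (0.155), and none passed with an estimated correlation. NF-kB also lost its call after quantile normalization (0.0568), and autophagy and lysosome with a trended and robust variance (0.0554).

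**Figure D2:**
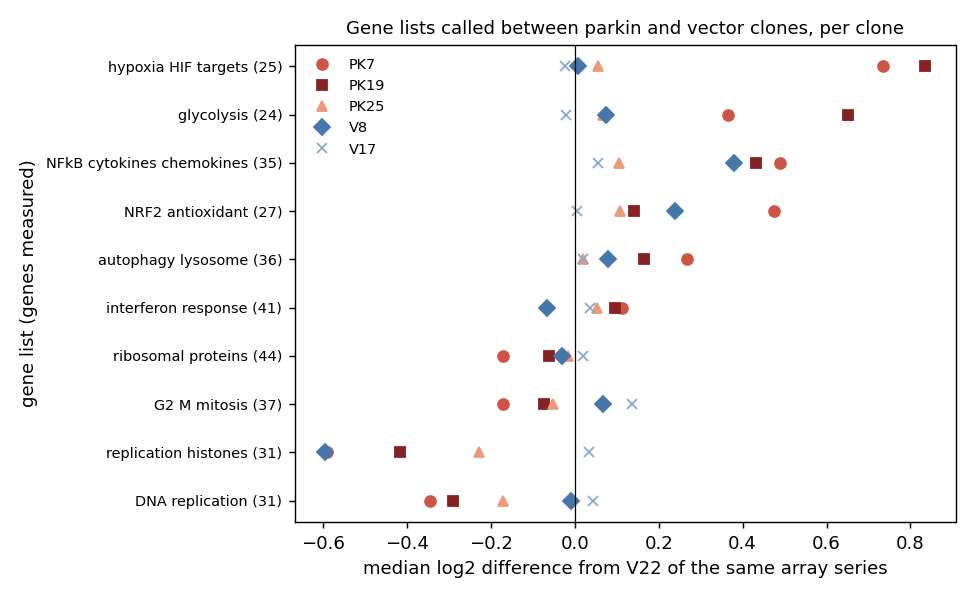
Median log2 difference of each clone from V22 of the same array series, for the 10 gene lists that passed between parkin and vector clones (measured genes in brackets). For hypoxia targets PK7 and PK19 stood at 0.73 and 0.84, and PK25, V8 and V17 lay near 0.

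KDR, which encodes the main receptor for VEGF, was at 6.64 ± 0.44 (SD, n = 3) in parkin clones and 8.35 ± 0.76 (SD, n = 2) in vector clones. Its log2 difference was -1.89 (SE 0.35) with 3 vector clones, and -1.71 with V17 and V22 counted once. The limma adjusted p of the former was 0.306 over all probe sets and 0.031 adjusted over the list alone for angiogenesis. SEMA3A, a repulsive guidance gene, differed by -1.59 (SE 0.38) and ACTA2, smooth muscle actin, by -1.77 (SE 0.39). CASP2, an apoptotic caspase gene, differed by -0.45 (SE 0.077), with an adjusted p of 0.023 adjusted over the list alone for apoptosis regulators. CCND1, cyclin D1, differed by -0.62 (SE 0.21), and its clone means were 10.49 in PK7, 10.68 in PK19, 11.04 in PK25 and 10.95 in V8. Among endothelial markers KDR, ERG (-0.46) and PECAM1 (0.43) passed when adjusted over the list alone, and a dimmer probe set of PECAM1 differed by -0.39. Among neuronal markers ELAVL4 (0.35) and DCX (0.31) passed when adjusted over the list alone, from dim probe sets with means of 3.49 and 4.75 in parkin clones. Of these calls over a list alone, those of KDR for angiogenesis, CASP2, ELAVL4 and DCX were lost with V17 and V22 counted once, and 2 genes passed among endothelial markers. Over all probe sets the adjusted p was then 0.560 for KDR, SEMA3A, ACTA2 and CASP2.

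The other 33 lists did not pass with the preset correlation. Of growth control, G1 cyclins and kinases had a median of -0.08 (adjusted p = 0.174), CDK inhibitors 0.07 (0.582), p53 targets 0.17 (0.108) and apoptosis regulators 0.00031 (0.779). Of mitochondria and protein turnover, mitophagy genes had a median of 0.08 (0.112), mitochondrial biogenesis -0.16 (0.226), nuclear genes of oxidative phosphorylation -0.05 (0.0982) and the proteasome 0.03 (0.841). Ubiquitin ligase and neddylation genes had -0.05 (0.378), heat shock chaperones 0.09 (0.582), the unfolded protein response 0.08 (0.231) and the ATF4 response 0.09 (0.779). Of signalling, receptor tyrosine kinase and PI3K genes had -0.03 (0.864), VEGF and angiogenesis 0.0032 (0.969), Wnt targets 0.08 (0.534), the Notch pathway 0.05 (0.617), YAP targets 0.13 (0.178), TGF-beta targets 0.04 (0.779) and immediate early genes 0.02 (0.766). Extracellular matrix genes had 0.11 (0.630), adhesion and migration 0.06 (0.609), the mesenchymal glioma subtype 0.08 (0.617), the proneural subtype 0.01 (0.867) and astrocyte and neural stem markers -0.0079 (0.867). Cholesterol synthesis had -0.07 (0.378), fatty acid synthesis 0.05 (0.595) and cancer-testis antigens 0.12 (0.108).

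Markers of other cell types did not pass either, with medians of 0.10 for blood (adjusted p = 0.115), 0.07 for epithelium (0.108), 0.07 for endothelium (0.906), 0.05 for neurons (0.234) and -0.03 for muscle (0.378). In the lists of angiogenesis, astrocyte markers, endothelium, the proneural subtype, the Notch pathway and apoptosis regulators, the median, the mean and the direction of the test did not all share a sign. The mitochondrially encoded list had none of its 13 genes among the probe sets with 1 symbol and was not tested.

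**Figure D3:**
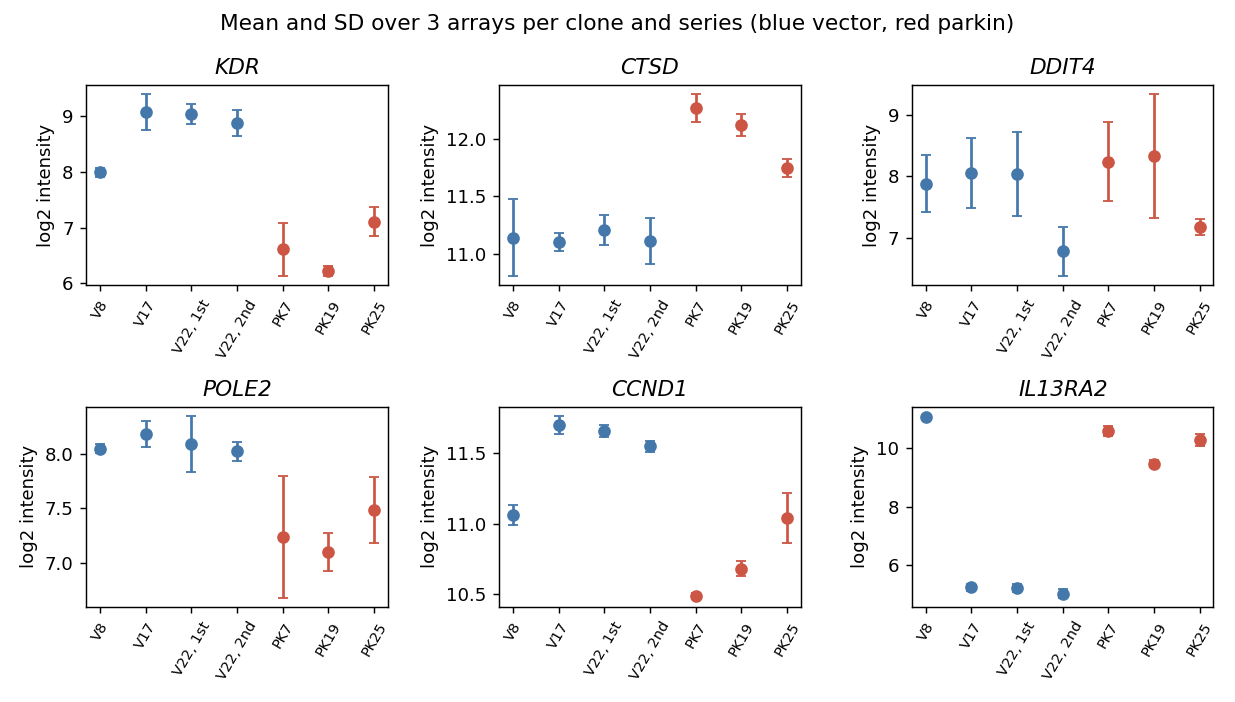
Mean log2 intensity with SD over 3 arrays for 6 genes in each clone, with V22 shown for each array series (blue vector, red parkin), before adjustment for the series. IL13RA2 was near 5.2 in V17 and near 11.07 in V8, and DDIT4 in V22 was 8.03 in the first series and 6.78 in the second.

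Within the second series alone, the same genes could be compared between the 3 parkin clones and V22 without a link between series. CTSD differed by 0.93 (SE 0.24), KDR by -2.23 (SE 0.37), POLE2 by -0.75 (SE 0.19) and ACTA2 by -1.99 (SE 0.60). DDIT4 differed by 1.13 (SE 0.52) and SEMA3A by -1.51 (SE 0.66). Probe set 8130645 had the smallest adjusted p, 0.200. The limma count was 0 (465 probe sets had an unadjusted p under 0.05), and it was 19 with arrays as observations and clone as a random block. Without the set 2 arrays and V22 set 5 the count was 1.

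Each clone was also compared with V22 of its own series, which asked how far single clones departed from a vector clone. IL13RA2, a decoy receptor for interleukin 13, was higher in all parkin clones and in the vector clone V8, by 5.60 in PK7 (SE 0.12), 4.46 in PK19 (SE 0.11), 5.27 in PK25 (SE 0.14) and 5.86 in V8 (SE 0.11). C1S, a complement protease gene, was higher by 5.25 in PK7, 5.35 in PK19 and 3.16 in V8, and MMP3, a matrix metalloproteinase gene, by 3.47, 4.26 and 2.96. PK7 also had higher C3 (5.05), TUSC3 (5.12) and CHI3L1 (3.83) and lower HSD17B2 (-3.39), LRRTM4 (-3.20) and ELAPOR2 (-3.17). PK19 had higher E2F7, a repressor of the cell cycle (5.13), and MAGEC1 (4.67), and lower ALDH7A1 (-3.99), CD24 (-3.88) and SRGN (-3.55).

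PK25 had higher MMP1 (2.41), PAPSS2 (1.17) and ABCC2 (1.27) and lower NCAM2 (-2.89), KDR (-1.77), RHOJ (-1.77), TAGLN (-1.65) and ACTA2 (-1.44). KDR was lower by -2.26 in PK7, -2.65 in PK19 and -1.05 in V8, and TAGLN by -2.28, -2.60 and -1.92. V8 had higher TRIML2 (3.27), HAS2, a hyaluronan synthase gene (3.10), and IL1B (2.98), and lower GABRA3 (-3.08), IGFBP5 (-2.82), SNORD113-4 (-3.12) and MEG3 (-2.17), the latter pair from an imprinted cluster. These genes, chosen from the largest changes after their values were seen, all passed an adjusted p under 0.05 in limma over the arrays. CCND1 was lower by -1.06 in PK7, -0.87 in PK19 and -0.60 in V8, and its difference of -0.51 in PK25 did not pass (adjusted p = 0.167).

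Of the hypoxia targets 12 rose in PK7 and 13 in PK19, with list medians of 0.73 and 0.84. In PK25 the median was 0.05 and no gene passed, and in V8 the median was 0.01 and 2 genes rose. Of the DNA replication genes 5 fell in PK7 (median -0.35) and 13 in PK19 (-0.29), PK25 had a median of -0.17 with no gene past the threshold, and V8 a median of -0.01. NF-kB genes had medians of 0.49 in PK7, 0.43 in PK19, 0.11 in PK25 and 0.38 in V8, with 18, 16, none and 9 genes risen. Extracellular matrix genes had a median of 0.40 in PK7 (15 rose and 4 fell), 0.04 in PK19 (8 rose and 11 fell), -0.15 in PK25 (1 rose and 1 fell) and 0.07 in V8 (11 rose and 1 fell). The mean of this list was 9.40 on the PK7 set 2 array, where the other parkin arrays had 8.38 to 8.89. With the preset correlation 16 lists passed in PK7, 10 in PK19, 9 in PK25 and 10 in V8. V17 had 1, the list of G2 and mitosis (median 0.14), though limma called no gene in that clone. With an estimated correlation none passed, and the smallest adjusted p was 0.0691 in PK7, 0.582 in PK19, 0.593 in PK25, 0.698 in V8 and 0.977 in V17.

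With an adjusted p under 0.05 and a change of at least 2-fold, limma called 598 probe sets in PK7 (372 higher and 226 lower), 754 in PK19 (416 and 338), 28 in PK25 (12 and 16) and 249 in V8 (147 and 102). In V17 the limma count was 0 (1165 probe sets, 4.32%, had an unadjusted p under 0.05). The SD of the log2 difference from V22 over all probe sets was 0.13 for V17, 0.21 for PK25, 0.29 for V8, 0.37 for PK7 and 0.41 for PK19. These comparisons share V22 arrays, so likeness between clones in their differences was not tested. The PK25 count was unstable, as it changed with whichever single array was left out. It was 4, 6 and 5 without V22 sets 4, 5 and 6, and 5, 53 and 15 without PK25 sets 1, 2 and 3. It was 3 without the set 2 arrays and V22 set 5, and the V8 count was 136 without set 3 and 259 with the set number as a block.

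**Figure D4:**
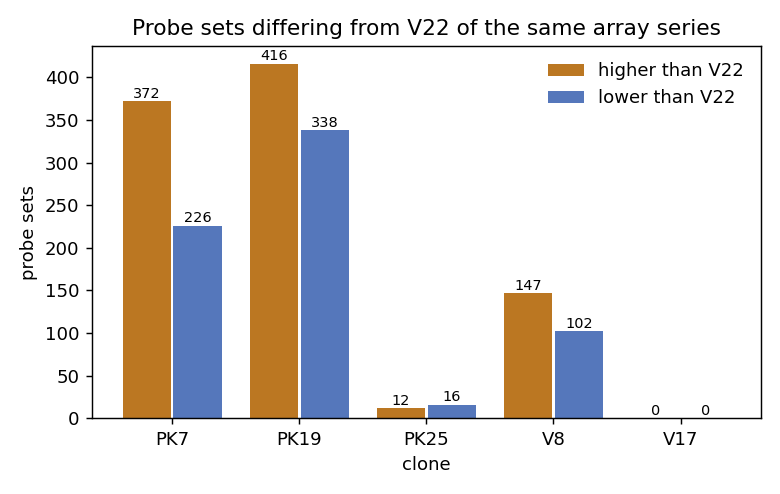
Number of probe sets higher (orange) or lower (blue) than V22 of the same array series, per clone, at a limma adjusted p under 0.05 and at least 2-fold. The counts ran from 416 higher and 338 lower in PK19 to 0 in V17.

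Among the 3 parkin clones the largest F was that of E2F7, which was at 10.19 in PK19, 5.18 in PK7 and 5.20 in PK25. GALNT5, a glycosyltransferase gene, was at 10.50 in PK7, 7.82 in PK25 and 4.67 in PK19. SRGN, a proteoglycan gene, was at 7.10 in PK19, 10.04 in PK7 and 10.68 in PK25, MRS2, a magnesium channel gene of mitochondria, at 7.99, 3.91 and 3.98, and PNLIPRP3 at 9.29, 4.62 and 4.70. By limma's F test, 4465 probe sets (16.6%) differed among the parkin clones, 1194 of them by at least 2-fold. Without set 1 the count was 1044 and without set 3 it was 1729, and with the set number as a block it was 4772.

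Among the 3 vector clones the genes with the largest F set V8 apart from V17 and V22. IL13RA2 was at 11.07 in V8, 5.24 in V17 and 5.21 in V22, TRIML2 at 8.81, 5.68 and 5.54, and GALC, the lysosomal galactosylceramidase gene, at 6.29, 3.97 and 3.69. MORC1 was at 6.03, 3.76 and 3.82, and SNORD113-3 at 3.97, 6.58 and 6.25. By limma's F test 1732 probe sets (6.43%) differed, 266 of them by at least 2-fold. The count was 258 without set 1, 1080 without set 2 and 217 without set 3, and 1846 with the set number as a block.

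V22 was measured in both series, which gave the size of the difference between series with the clone held fixed. DDIT4 differed by -1.25 and ACTA2 by -0.81 between the second and the first series, and IL13RA2 by -0.19 and CTSD by -0.10. Of these none passed, and the limma count was 0 (3570 probe sets, 13.2%, had an unadjusted p under 0.05), with a smallest adjusted p of 0.148. The count was 107 with a trended and robust variance and 3 without the set 2 arrays and V22 set 5.

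Differences from V22 were shared by neighbouring genes on several chromosomes. In PK7 the run from TOB2 to SCO2 on chromosome 22 had a median of -0.53 and the run from BAK1 to RRP36 on chromosome 6 a median of -0.60. In PK19 the run from HEATR5A to FERMT2 on chromosome 14 had a median of -0.84, that from BAK1 to RRP36 -0.75 and that from RNF138 to RELCH on chromosome 18 a median of 0.68. In V8 the run from OBI1 to CHAMP1 on chromosome 13 had -0.71, that from BAK1 to RRP36 -0.53 and that from FOXJ2 to CCDC91 on chromosome 12 a median of 0.63, where PK25 had 0.31. Of 178 runs, 20 lay beyond 0.3 in either direction in PK19, 16 in PK7, 13 in V8, 3 in PK25 and none in V17.

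Across genes, which are not independent replicates, the correlation between differences of expressed genes 10 places apart was 0.176 in PK7, 0.149 in PK19, 0.207 in PK25 and 0.276 in V8. Each had a permutation p of 0.001, the smallest that the permuted gene orders can give, and so did the difference between parkin and vector clones (0.144). It was 0.022 in V17 (permutation p = 0.028) and 0.031 for V22 between series (permutation p = 0.002). Adjusted over the 7 correlations computed, the largest permutation p was 0.028 and that of the former 5 was 0.0014. Deviations of single arrays from their clone mean gave correlations of up to 0.164.

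**Figure D5:**
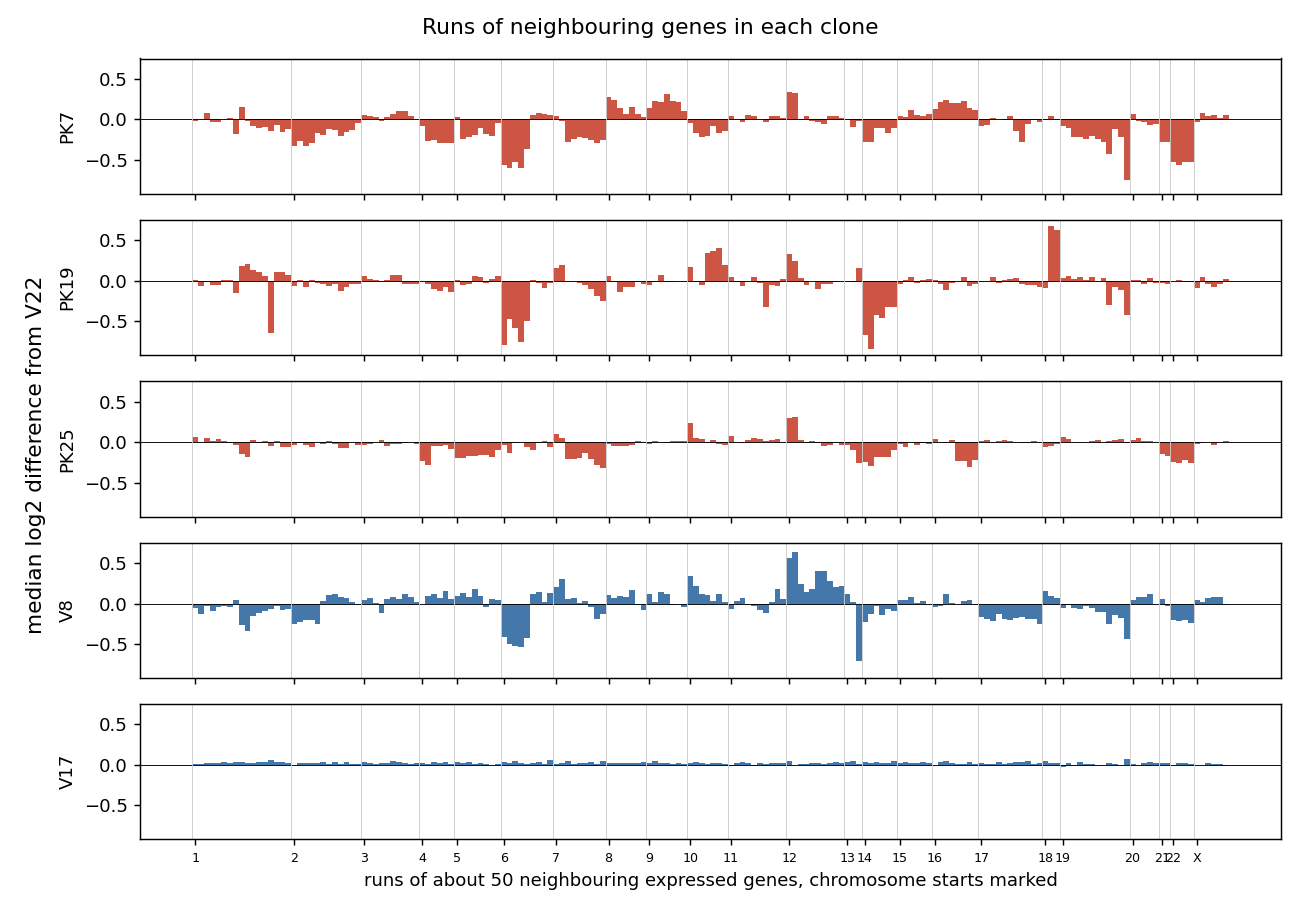
Median log2 difference from V22 of the same series over 178 runs of about 50 neighbouring expressed genes, in chromosome order, for each clone (red parkin, blue vector). V17 stayed between -0.02 and 0.07, and the other clones held runs as low as -0.84 and as high as 0.68.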

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

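Except for the correlation of separate arrays, the removal of array noise from all probe sets of PK25, the histone neighbours and the counts over other splits, the tests in this part were chosen only after the result was seen.

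Of 94 groups of arrays tested for a lone value, 10 held such an array, where 4.7 are expected by chance. PK7 set 2 stood apart from the other parkin arrays in list means of G1 cyclins (8.30, others 8.55 to 8.69), DNA replication (8.98, others 9.34 to 9.56), extracellular matrix (9.40, others 8.38 to 8.89) and the proteasome (10.42, others 10.68 to 10.86). V22 set 2 stood apart from the other V22 arrays in hypoxia targets (9.43, others 8.63 to 8.92), the unfolded protein response (9.04, others 8.90 to 8.94) and blood markers (5.63, others 5.48 to 5.51). V22 set 5 stood apart in NF-kB genes (6.14, others 6.24 to 6.28). PK25 set 3 stood apart in blood markers (5.77, others 5.45 to 5.61) and epithelial markers (6.08, others 5.72 to 5.88). The 3 parkin clones differed from each other in 4465 probe sets by the F test.

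Differences of clones from V22 lay in runs of neighbouring genes. Array noise is argued against as the source, because run medians from separate arrays of a clone correlated at 0.615 or more in PK7, PK19, PK25 and V8, and at most at 0.153 in V17. Introduced parkin alone is also argued against, because the vector clone V8 had 13 runs beyond 0.3 and the parkin clone PK25 had 3. Gained or lost chromosome segments stay open as a source: in the 52 runs beyond 0.3 a median of 92% of the genes went one way (78% to 100%), which decides nothing because runs chosen by their median hold most genes to one side by construction, and copy number was not measured here. Separate selection of each clone stays open as well, as untested.

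PK25 lay closer to V22 than PK7 and PK19 did. Noisier PK25 arrays, which could hide differences, are argued against, because with array noise removed the SD of the difference from V22 was 0.144 in PK25 (0.112 to 0.176 over left-out arrays), 0.347 in PK7, 0.384 in PK19 and 0.242 in the vector clone V8. A mix-up with V8, V17 or V22 is argued against, because with array noise removed the run medians of PK25 differed from those of each with an SD of at least 0.0905, where V22 between series had at most 0.0429. A vector clone that was not measured stays open, though on 8130645, which had the smallest p without PK25 as well, the lowest PK25 array lay 4.32 above the highest vector array, as this is a single probe set. Of 38 probe sets called without PK25, PK25 lay beyond all vector clones towards PK7 and PK19 in 28. Its median place was 0.124 of the way from the vector mean to that of PK7 and PK19. The choice favours probe sets with little spread among vector clones, so it decides nothing. What sets PK25 nearer to V22 stays open otherwise too, including a biological difference between the clones, which no group of the design tests.

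Of the lists that shifted between parkin and vector clones, for DNA replication shared shifts of neighbouring genes are argued against as the whole source. The median was -0.26 after subtraction of the neighbours, and the call held with the preset correlation. The set 2 arrays and V22 set 5 are argued against as the whole source too. They include PK7 set 2, which stood apart in this list. Without them the median was -0.25, and the call held with the preset correlation. PK25 set 3, which stood apart in blood and epithelial markers, was kept in. For hypoxia targets the median was 0.53 after subtraction of the neighbours and 0.18 without the set 2 arrays and V22 set 5, both past the threshold. The arrays left out may therefore account for part of its size. The rise may also belong to PK7 and PK19 alone, because PK25 had a median of 0.055 and V8 one of 0.0088. That difference between clones was not tested for lists. The histone fall may be part of a shift of chromosome 6, because other genes around the cluster had a median of -0.63 in PK7 and PK19, though in PK25 the histones had -0.23 and their neighbours -0.0077, and histone genes on other chromosomes, which the test also needed, were not in the list. For histones introduced parkin is argued against as the whole source, because in V8, a vector clone, the median against V22 was -0.394 or lower in each of 3 separate array pairs, and in PK25 it was -0.258 at its lowest. Culture state stays open for all of these lists and introduced parkin for DNA replication and hypoxia targets, and parkin and array series are confounded except through V22.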

How the results depend on the processing

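The settings chosen only after the data were seen were leaving out the set 2 arrays and V22 set 5, V17 and V22 counted once, the subtraction of neighbours with or without histone genes among them, single arrays of the first series left out, and set-number blocks in the F tests and clone comparisons. No result reversed its direction past the threshold. Over all settings 117 of 152 recomputed counts stayed within 1.5 times the reported count, and of the settings of named genes 438 kept their side of the threshold and 26 gained a call. Of the settings of lists, 781 kept their side, 27 gained a call and 52 lost it. The cause was not tested except where fewer arrays, fewer probe sets or a stricter threshold set it.

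Parkin against vector clones, 1 probe set, became 22 with clone as a random block, 885 with clones as fixed terms, 1343 with the set-number block and no adjustment for the series, and 0 with 1 probe set per gene, which leaves out 8130645 because it has no symbol. Without each clone in turn it ranged from 1 to 38. Set numbers did not pair vector arrays of the first series with parkin arrays, which within the same set correlated at 0.0225, 0.0818 and -0.0060. Whether V22 arrays of the second series pair with parkin arrays was not tested. Arrays of the first series correlated at 0.0591 to 0.216 within a set and at -0.141 to 0.0533 between sets. Parkin arrays correlated at -0.0917 to 0.381 within a set (0.145 to 0.381 in set 2) and at -0.365 to 0.323 between sets. The 10 lists became 6 without adjustment for the series, 6 with vector arrays of the first series and 6 with the set-number block, the latter 2 also without that adjustment. They became 0 with an estimated correlation, and ranged from 4 to 14 without each clone. Parkin clones against V22 within the second series went from 0 to 19 with clone as a random block and to 1 without the set 2 arrays and V22 set 5.

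The F test among parkin clones gave 1194 with a 2-fold threshold and 1044 to 4166 without each set. Among vector clones it gave 266 with that threshold, 217 to 1080 without each set and 1080 without set 2. Against V22 with no fold threshold the counts were 3171 in PK7, 3864 in PK19, 52 in PK25 and 1319 in V8. Without single arrays or sets PK25 ranged from 4 to 53 and V8 from 136 to 260, and PK25 had 3 without the set 2 arrays and V22 set 5. V22 between series gave 107 with a trended and robust variance and 3 without those arrays. With vector arrays of the first series alone, 12 of the 24 named genes shrank by more than 1.5 times, as given with the genes.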

Other observations

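The medians per chromosome were computed only after the result was seen, and the test of histone neighbours and the splits of samples were chosen before.

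Medians of whole chromosomes lay away from 0 in some clones. In PK7 the median log2 difference from V22 was -0.53 on chromosome 22, -0.29 on chromosome 21 and 0.20 on chromosome 9. In PK19 it was -0.49 on chromosome 14, -0.36 on chromosome 6 and 0.25 on chromosome 18, but on the latter 2 only part of the runs was shifted, as on chromosome 6 the run from EEF1A1 to CRYBG1 had 0.01 and on chromosome 18 the run from USP14 to TRAPPC8 had -0.08. In V8 it was 0.30 on chromosome 12 and -0.21 on chromosome 22, and in PK25 it was -0.25 on chromosome 22 and -0.20 on chromosome 14. In V17 no chromosome went beyond 0.04.

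Histone genes of chromosome 6 and their neighbours were also lower in the vector clone V8, with medians of -0.60 for the 31 histone genes and -0.53 for 50 other expressed genes around them. In V17 these medians were 0.03 and 0.04.

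Other splits of the samples gave the following counts. For parkin against vector clones, 2 of the 10 splits of 6 clones called at least 1 probe set, and 10 splits are too few for a share under 0.05. The real count was 1 and the highest other 235, from the split of V8, PK7 and PK19 against V17, V22 and PK25, which called many more genes than the real split and points to a structure of the samples. For gene lists, 5 of 10 splits called at least 10 lists, and the same split called the highest other number, 16. In the F test among parkin clones only the real split among 100 reached 4465 (highest other 842), a share under 0.05. As every other split mixes arrays of different clones, this shows only that arrays of a clone were more alike than arrays of different clones. In the F test among vector clones 2 of 100 splits reached 1732, the real split and another at 1809, so the share was under 0.05 but the real count was not the highest. Both F tests regroup arrays that may be technical repeats, so these shares tell nothing of clones as independent samples. For V22 between series all 10 splits gave 0, and for V17 against V22 all 10 gave 0. For PK7 (598), PK19 (754), PK25 (28) and V8 (249) against V22 only 1 of 10 splits, the real split, gave such a count, the highest other was 0, and 10 splits are too few for a share under 0.05.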
